A study of Homo sapiens with 6 samples.

How the data were processed

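RNA of 6 libraries was measured by sequencing, 3 from RKO cells carrying a hairpin against TRIP6 (shTRIP6) and 3 from RKO cells carrying a scrambled hairpin (shControl). The control labels give the genotype as WT and the treatment as a scrambled hairpin, and the title of the series names the controls as WT only. The treatment was followed here. Per the labels, cells were selected with puromycin at 5 µg/ml from 36 h after infection for 2 to 3 weeks, and total RNA was taken with a mirVana kit. The deposited values were raw read counts per gene symbol, with 27980 symbols in each library and no normalization. The submitters' processing notes name TopHat2, edgeR, limma and the genome build hg38 without role, order or version. The counting tool, its annotation and its strand setting are not given in the sources used here.

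Groups and replicate numbers were taken from the labels. The counts were whole numbers and summed to 29605764 to 32089298 per library. A single count was worth 0.0312 to 0.0338 CPM, the usual scaling of counts to library size. A gene with 0 counts was given a floor of 3 counts, which was 0.0935 to 0.101 CPM in a library and 0.0317 CPM over the shTRIP6 group. Where a gene had 0 counts in all shTRIP6 libraries, its fall was computed against the floor over the group and written as at least that size. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Scaling factors from TMM ranged from 0.992 to 1.01, and the 10 most abundant genes took 5.02% to 5.56% of the counts. CPM values used the library sizes scaled by TMM. Replicate agreement was checked by chi-square per degree of freedom over genes with 20 counts or more.

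The groups were compared in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test with group as the only term). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change was its size divided by the square root of the F statistic. Gene lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists, where at least 3 members were tested. Of 39 lists fixed before the data were examined, 36 could be tested. They covered YAP and TAZ targets, the Hippo core, zyxin-family proteins, focal adhesion, integrins, matrix, mesenchymal, epithelial and colonic markers. Further lists held WNT, NF-kB, immediate early, TGF-beta, lysophosphatidic acid, p53, G1/S, G2/M, CDK inhibitor, MYC and ribosomal protein genes. The others held interferon, MHC class I, cholesterol, fatty acid, ATF4, endoplasmic reticulum chaperone, heat shock, hypoxia, NRF2, FOXO, apoptosis, telomere, autophagy, oxidative phosphorylation, mitochondrially encoded, histone, fibroblast, leukocyte and endothelial genes.

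Genes named in the text were chosen by a rule also fixed before the data were examined. TRIP6 came first. Then came the 12 largest rises and the 12 largest falls among called genes whose libraries did not overlap between the groups and whose mean was 10 CPM or more, leaving out clone-based, LINC and open-reading-frame type symbols. For each list up to 2 rises and up to 2 falls among called members with a mean of 1 CPM or more were named. Some genes that the rule takes are not reported here. Genes outside this rule are said to have been named after their values were seen.

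Coordinates and exon overlaps came from GENCODE release 29 (GRCh38), in which 25811 of the 27980 symbols were found, 25770 by name and 41 through an older or newer symbol. Of the tested genes, 14840 were matched and 5336 had exons overlapping those of another gene of the table. Counts of 97 tested genes were identical to those of another gene in all 6 libraries.

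The edgeR test was checked on simulated data of the same size with 15311 genes fitted, 50 of them changed at each size. It recovered 28% of genes changed 1.2-fold, 62% at 1.5-fold, 82% at 2-fold and 98% at 4-fold, with 6 false calls (4.26% of calls). The list test called a simulated changed list and 0 of 40 unchanged lists. Genes were simulated independently with 200 of them changed, a far smaller share than the 60.1% called in the data. These checks therefore cover neither correlation between genes nor the power of the real comparison. The test for runs of neighbouring genes was checked on 20 simulations of 12875 genes, with 0 false calls, and called all 20 in which 6 blocks of 5 genes had been removed. The test of windows of 50 genes made 2 false calls in 20 simulations and called all 20 with a shift of 0.4 on the log2 scale.

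Alternatives fixed before the data were examined were RLE, upper-quartile and no scaling, no low-count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each replicate, an estimated correlation and fry. Added after the data were seen were the genes with no overlapping exons, and the lists without genes at 5% or less of the shControl level. The run test used protein-coding genes with a mean of 0.5 CPM or more and 10000 permuted gene orders, and the window test genes of 5 CPM or more and 1000 permuted orders. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.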

Results

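RNA from RKO cells, a poorly differentiated human colon carcinoma line, was sequenced in 6 libraries. In 3 libraries the cells stably carried a lentiviral short hairpin RNA against TRIP6 (shTRIP6), and in 3 they carried a scrambled hairpin (shControl). TRIP6 encodes a LIM-domain adaptor protein of the zyxin family, which is found at focal adhesions and in the nucleus. The shTRIP6 libraries held 31096598 to 32089298 counts and the shControl libraries 29605764 to 30949334 counts. A single count was worth 0.0312 to 0.0338 CPM, the usual scaling of counts to library size. A gene with no count in a library could stand at up to 0.0935 to 0.101 CPM there, which is the floor of 3 counts. Counts of the replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 3.05 to 4.60 between shTRIP6 libraries and 4.81 to 11.8 between shControl libraries. Across the groups the same measure was 119.5 to 136. The labels call the replicates biological, and nothing in them says that they came from separate cultures, so p-values then measure only the spread between these libraries. Values are mean CPM ± SD with n = 3 per group, and fold changes are log2 of shTRIP6 over shControl ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p.

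The comparison of shTRIP6 with shControl asks how the transcriptome of RKO cells differs when TRIP6 is depleted. Whether both groups came from the same stock of cells is not given in the sources used here, and any difference between stocks would fall on the same split as the hairpins. Differences of genes and lists below are therefore between the groups, and are not assigned to TRIP6. TRIP6 itself lies on chromosome 7 from 100867138 to 100873454 on the plus strand (GRCh38, a protein-coding gene, ENSG00000087077.13). Its level was 19.5 ± 0.203 CPM in shTRIP6 against 80.3 ± 6.27 CPM in shControl, which left 24.3% of the control level (log2 fold change -2.04 ± 0.07, edgeR adjusted p = 1.25e-14). All 3 shTRIP6 libraries lay below all 3 shControl libraries. The exons of TRIP6 overlap those of the microRNA gene MIR6875.

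**Figure D1:**
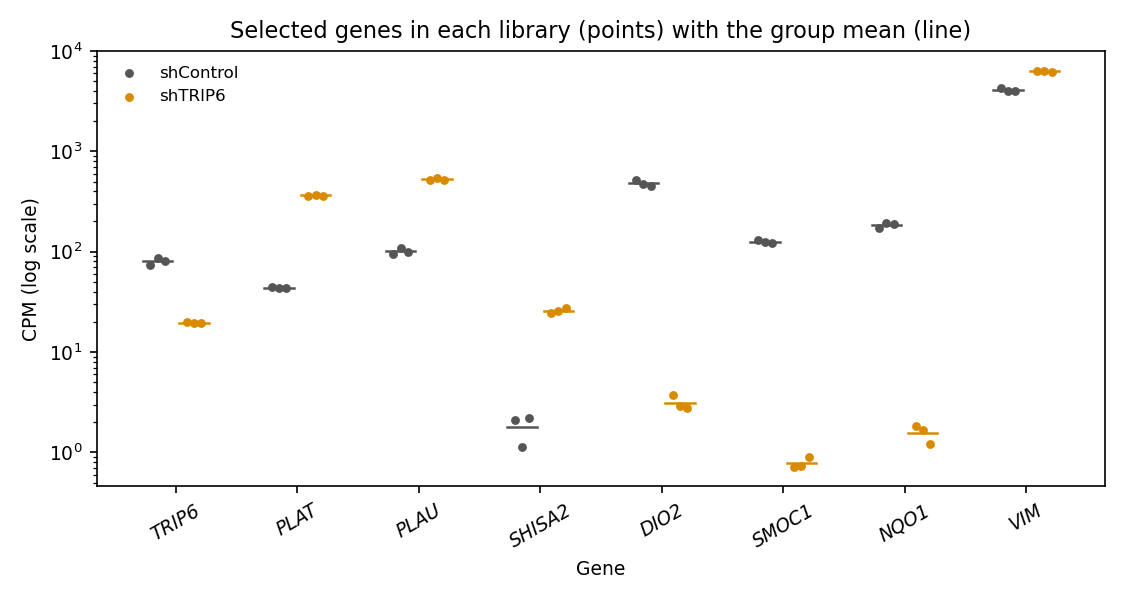
Level of 8 genes in each library, in CPM on a log axis; points are the 3 libraries of a group, the horizontal lines are group means, and the colours separate shControl from shTRIP6. TRIP6 stands at 19.5 CPM in shTRIP6 and 80.3 CPM in shControl, and for each gene plotted the libraries of the 2 groups do not overlap.

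Of 15473 genes tested, 4487 were higher and 4820 were lower in shTRIP6, and 6166 did not pass the adjusted threshold of 0.05 in edgeR. The rises were mostly small, with a median log2 fold change of 0.45 among genes called higher and -0.61 among genes called lower. At least 2-fold rises numbered 678 and at least 2-fold falls 1632. At 10-fold or more the counts were 24 rises and 645 falls. Among genes at 1 CPM or more in the higher group, 441 stood at 5% or less of their shControl level in shTRIP6, and 6 stood at 5% or less of their shTRIP6 level in shControl. Among these, named after their values were seen, were HOXA7, HSD11B1, INSC, LZTS1 and WT1. The 3 values of a group lay wholly to a side of the other group's in 65.3% of tested genes, where chance gives 10%. The first principal component held 88.6% of the variance and separated the groups.

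**Figure D2:**
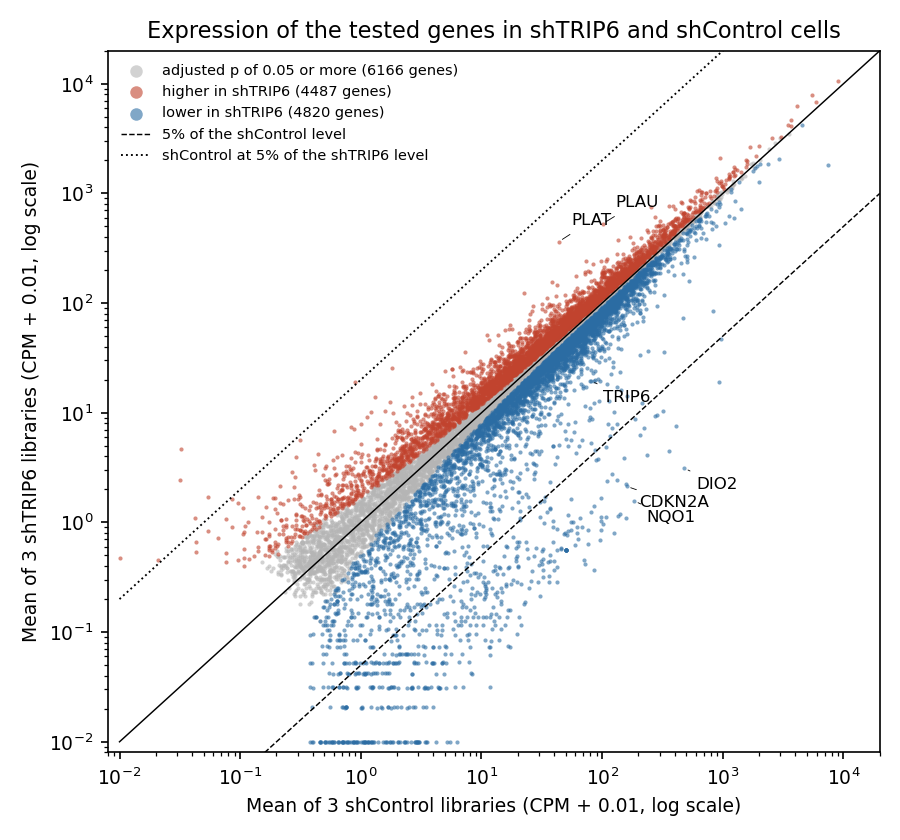
Mean CPM of each tested gene in shTRIP6 (vertical) against shControl (horizontal), with 0.01 added and both axes on a log scale; red points were higher and blue points lower in shTRIP6, and grey points did not pass the threshold. The dashed line marks 5% of the shControl level, with 441 genes of 1 CPM or more in shControl on or below it, and the dotted line marks the reverse, with 6 genes of 1 CPM or more in shTRIP6 on or above it.

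Among called genes with a mean of 10 CPM or more, chosen by the fixed rule, the 12 largest rises included both plasminogen activators. PLAT, the tissue-type activator, stood at 363 ± 5.56 CPM in shTRIP6 against 43.8 ± 0.316 CPM in shControl (log2 fold change 3.05 ± 0.05, adjusted p = 8.10e-20), and PLAU, the urokinase-type activator, stood at 528 ± 10.6 CPM in shTRIP6 against 101 ± 7.29 CPM in shControl (log2 fold change 2.39 ± 0.05, adjusted p = 8.99e-18). The largest of these rises was that of SHISA2, at 25.8 ± 1.44 CPM in shTRIP6 against 1.80 ± 0.591 CPM in shControl (log2 fold change 3.84 ± 0.16). GLUL, glutamine synthetase, rose to 51.6 ± 2.81 against 11.1 ± 0.929 CPM, and RAB3B, a small GTPase of vesicle secretion, rose to 155 ± 7.83 against 38.1 ± 0.569 CPM. The microtubule plus-end protein gene SLAIN1 (log2 fold change 2.27), the phosphodiesterase gene ENPP4 (2.23), MELTF, which encodes melanotransferrin (2.00), the adaptor gene APBA2 (1.99) and the acetylcholine receptor subunit gene CHRNB1 (1.90) rose as well. MAGED4 and MAGED4B rose by the same 2.14, with identical counts in each library, so these near-identical copies cannot be separated by their counts. Exons of PLAU overlap those of C10orf55 and exons of MELTF those of MELTF-AS1. Of the 163 genes chosen by the fixed rule, 52 have exons that overlap those of another gene of the table, and the strand setting of the counting is not given in the sources used here.

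The 12 largest falls among called genes with the same mean of 10 CPM or more, also chosen by the fixed rule, left each gene at less than 1% of its shControl level. Genes with a lower mean, some with larger fitted falls, were not ranked. DIO2, a deiodinase that activates thyroid hormone, stood at 3.13 ± 0.505 CPM in shTRIP6 against 479.7 ± 39.3 CPM in shControl (log2 fold change -7.26 ± 0.09, adjusted p = 3.06e-21). SMOC1, a secreted calcium-binding matrix protein gene, stood at 0.786 ± 0.0993 CPM in shTRIP6 against 126 ± 5.13 CPM in shControl (log2 fold change -7.32 ± 0.10), and GDA, guanine deaminase, at 1.09 ± 0.163 against 158 ± 3.91 CPM (log2 fold change -7.17 ± 0.09). FOLR1, the folate receptor alpha gene, had the largest fitted fall of these 12, -7.87, from 85.4 to 0.359 CPM. The somatostatin receptor gene SSTR1 (-7.46), the splicing regulator gene MBNL3 (-7.29), the retinoic acid hydroxylase gene CYP26B1 (-7.27), the sodium-chloride cotransporter gene SLC12A3 (-7.25), TMTC1 (-7.13), the potassium channel gene KCNK1 (-7.03), IGFL2-AS1 (-7.03) and the actin nucleator gene COBL (-6.95) fell on the log2 scale by similar amounts. Each of these 12 genes kept 12 to 295 counts summed over the 3 shTRIP6 libraries. Exons of DIO2 overlap those of DIO2-AS1.

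Targets of the co-activators YAP and TAZ, whose activity TRIP6 has been linked to, were higher as a group. In this list 18 of 23 tested members rose and 3 fell (camera with a preset correlation, adjusted p = 4.88e-06, and adjusted p = 0.158 with an estimated correlation). CCDC80 stood at 749 ± 13.2 CPM in shTRIP6 against 254 ± 14.2 CPM in shControl and NT5E, the ecto-nucleotidase CD73, at 401 ± 1.81 against 171 ± 8.91 CPM. The textbook targets CTGF and CYR61, named after their values were seen, rose by 1.03 and 0.90 on the log2 scale. RBMS3 fell by 1.28 and FOXF2 fell by 0.48. Of the Hippo pathway core, 5 of 18 tested members rose and 7 fell (camera adjusted p = 0.970), with WWTR1, the TAZ gene, at a log2 fold change of -0.66, TEAD2 at -0.63, and the kinase and scaffold genes STK3 and MOB1B at 0.42 and 0.40. Of the other zyxin-family LIM proteins, 3 of 8 tested members rose and 3 fell (camera adjusted p = 0.704), with TES at -1.09, FBLIM1 at -0.77, LPP at 0.29 and LIMD1 at 0.23. Of the focal adhesion and actin crosslinking genes, 13 of 30 tested members rose and 11 fell (camera adjusted p = 0.695). The actin regulator ENAH, a partner of zyxin-family proteins, fell to 22.6 ± 1.51 against 119 ± 3.97 CPM and FERMT2, kindlin-2, to 38.0 ± 2.41 against 91.6 ± 9.11 CPM. The myosin light chain gene MYL9 and CSRP1 rose by 0.96 and 0.73. Of the integrins, 4 of 17 tested members rose and 8 fell (camera adjusted p = 0.105), with ITGB8 at -2.55, ITGA1 at -1.75, ITGA4 at 1.05 and ITGB2 at 1.03. The integrin list passed camera, as lower, in DESeq2 (adjusted p = 0.0385) and without the genes at 5% or less of the shControl level (adjusted p = 0.0255), in a range of 0.0255 to 0.160 over the camera alternatives.

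Extracellular matrix genes were lower as a group but divided in direction. Here 9 of 25 tested members rose and 13 fell (camera adjusted p = 4.88e-06, and adjusted p = 0.158 with an estimated correlation). COL12A1 stood at 9.57 ± 0.170 CPM in shTRIP6 against 285 ± 6.13 CPM in shControl and LAMA5 at 9.33 ± 1.98 against 273 ± 6.77 CPM, both below 5% of the control level. COL18A1 and COL6A2 rose by 1.57 and 1.45. The call was lost in limma-voom (adjusted p = 0.179) and without the genes at 5% or less of the shControl level (adjusted p = 0.439), in a range of 4.26e-08 to 0.439 over the camera alternatives. Fibroblast markers, fixed as markers of another cell type and sharing COL1A1 with the matrix list, were also lower as a group. Here 2 of 11 tested members rose and 7 fell (camera adjusted p = 0.00102, and adjusted p = 0.191 with an estimated correlation). This call was lost in limma-voom (adjusted p = 0.0622, in a range of 0.000269 to 0.0622 over the camera alternatives). The median log2 fold change was -3.07 with the genes at 0 counts set at their floor. FAP stood at 0.328 ± 0.0763 against 15 ± 1.33 CPM and MFAP5 at 0.434 ± 0.202 against 10.2 ± 1.69 CPM. DCN and POSTN, named after their values were seen, had no count in shTRIP6 and were at least 32.7-fold lower and at least 38.5-fold lower against a floor of 3 counts over the group. PDGFRB and THY1 rose by 1.02 and 0.78. Of the mesenchymal markers, 3 of 14 tested members rose and 10 fell (camera adjusted p = 0.225). VIM, the mesenchymal intermediate filament gene, rose to 6273 ± 129 against 4105 ± 155 CPM. MMP2 and S100A4, at under 5 CPM in both groups, fell by 2.35 and 2.04. Exons of VIM overlap those of VIM-AS1, whose counts came to 41.7% of those of VIM.

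Epithelial junction and keratin genes were lower as a group, with 3 of 18 tested members higher and 9 lower (camera adjusted p = 0.0225, and adjusted p = 0.248 with an estimated correlation). CLDN1, a tight junction claudin gene, stood at 8.83 ± 0.762 CPM in shTRIP6 against 82.8 ± 6.59 CPM in shControl, and TJP3 fell to 0.0534 ± 0.0665 against 2.34 ± 0.428 CPM. The simple-epithelium keratin gene KRT19 rose to 50.7 ± 3.15 against 13.8 ± 2.27 CPM and OCLN rose to 10.7 ± 0.299 against 3.62 ± 1.24 CPM. The call was lost in limma-voom (adjusted p = 0.142, in a range of 0.00478 to 0.142 over the camera alternatives). Of 20 colonic differentiation markers only the carbonic anhydrase gene CA2 had enough counts to be tested, and it rose to 7.07 ± 0.639 against 0.865 ± 0.354 CPM (log2 fold change 3.02 ± 0.25).

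TGF-beta and SMAD targets were lower as a group. In this list 3 of 16 tested members rose and 11 fell (camera adjusted p = 4.25e-11, and adjusted p = 0.0508 with an estimated correlation). The inhibitory SMAD gene SMAD6 stood at 0.351 ± 0.150 CPM in shTRIP6 against 12.4 ± 1.11 CPM in shControl and the cell-cycle inhibitor gene CDKN2B at 2.22 ± 0.678 against 159 ± 6.35 CPM. CDKN2B lies in a run of 5 neighbouring genes on chromosome 9 that were all nearly absent, as described below. The list passed in all 15 camera alternatives (adjusted p up to 0.00156), which include leaving out genes at 5% or less of the shControl level. The ligand gene TGFB1 rose by 0.55 on the log2 scale. Of the WNT and beta-catenin targets, 4 of 13 tested members rose and 5 fell (camera adjusted p = 0.695), with MYC at 214 ± 14.4 against 299 ± 23 CPM, BAMBI at -0.94, SP5 at 1.33 and TNFRSF19 at 1.13. Of the NF-kB targets, 7 of 20 tested members rose and 10 fell (camera adjusted p = 0.273), with TNFAIP2 at 33.6 ± 1.01 against 206 ± 12.6 CPM, the metalloproteinase gene MMP9 at -2.26 and the chemokine genes CXCL1 and CXCL3 at 0.71 and 0.76. The call of CXCL3 was lost without shTRIP6 replicate 2 (adjusted p = 0.102), shTRIP6 replicate 3 (0.0634) or shControl replicate 2 (0.0528), in a range of 0.0161 to 0.102 over its alternatives. Of the immediate early and AP-1 genes, 7 of 20 tested members rose and 9 fell (camera adjusted p = 0.704), and the AP-1 subunits went both ways: FOSL1 rose to 809.6 ± 21.7 against 458 ± 60.2 CPM, while JUNB fell to 19.4 ± 0.652 against 95.4 ± 3.39 CPM and JUND fell by 1.23. IER3 rose by 0.81. Of the genes for receptors and enzymes of lysophosphatidic acid, 5 of 11 tested members rose and 4 fell (camera adjusted p = 0.738), with LPAR2, whose product binds TRIP6, at -0.72, AGPAT2 at -0.87, ENPP2 at 0.71 and MAGI3 at 0.38.

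Genes of the G1/S transition were higher as a group by small amounts. Here 16 of 26 tested members rose and 1 fell (camera adjusted p = 0.0155, and adjusted p = 0.158 with an estimated correlation). The ribonucleotide reductase gene RRM2 stood at 872 ± 11 against 534 ± 19.4 CPM, with the cyclin gene CCNE2 at a log2 fold change of 0.64 and ORC1 at -0.24. The call of ORC1 was lost without shTRIP6 replicate 1 (adjusted p = 0.0616, in a range of 0.00513 to 0.0616 over its alternatives). Of the replication-dependent histone genes, 0 of 13 tested members rose and 9 fell (camera adjusted p = 0.000276, and adjusted p = 0.158 with an estimated correlation). HIST1H2BD stood at 3.38 ± 0.353 against 27.1 ± 1.96 CPM and HIST2H2BE at 2.5 ± 0.871 against 14.3 ± 1.51 CPM. As a class, mRNAs of replication-dependent histone genes mostly lack poly(A) tails, and the list was fixed as a sign of RNA selection. Whether RNA selection differed between the groups was not tested, and single members need not follow the class. Of the G2/M genes, 15 of 30 tested members rose and 9 fell (camera adjusted p = 0.315), with CDCA3 at 0.73, HMMR at 0.69, KIF20A at -0.49 and BUB1B at -0.45. Among CDK inhibitors and D-type cyclins 6 of 12 tested members rose and 5 fell (camera adjusted p = 0.00187, and adjusted p = 0.158 with an estimated correlation). Its test and mean log2 fold change were negative (-1.47 with the gene at 0 counts set at its floor) and its median positive (0.14). CDKN2A fell to 2.13 ± 0.379 against 160.0 ± 8.89 CPM, CDKN2B fell as given above, and CCND2 had no count in shTRIP6, at least 64.1-fold lower than its 2.03 ± 0.227 CPM in shControl. CDKN2A and CDKN2B are neighbours in the same chromosome 9 run, so their falls may not be independent. CDKN2D and CCND3 rose by 1.39 and 0.67. This call was lost in DESeq2 (adjusted p = 0.0817) and limma-voom (adjusted p = 0.895), and its direction turned without the genes at 5% or less of the shControl level (median log2 fold change 0.29, adjusted p = 0.431), in a range of 0.000167 to 0.895 over the camera alternatives.

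The cytosolic ribosomal proteins were higher as a group, with 19 of 29 tested members higher and 2 lower (camera adjusted p = 0.0225, and adjusted p = 0.650 with an estimated correlation). RPL10 stood at 1395 ± 33.4 against 878 ± 98.6 CPM and RPLP2 at 279 ± 11.9 against 184 ± 16.1 CPM. RPS24 and RPL37 fell by 0.35 and 0.32. Ribosomal protein genes have many processed pseudogenes, which reads can be shared with. Of the MYC targets of ribosome biogenesis, 11 of 20 tested members rose and 2 fell (camera adjusted p = 0.105), with BOP1 at 0.62, RRS1 at 0.56, DDX21 at -0.25 and DKC1 at -0.12. The call of DKC1 was lost in 7 of 14 alternatives, in a range of 0.0192 to 0.199, with the highest adjusted p under upper-quartile scaling. It was lost without shTRIP6 replicate 1 (adjusted p = 0.0594), shTRIP6 replicate 2 (0.185), shTRIP6 replicate 3 (0.106) or shControl replicate 3 (0.0853). Of the p53 targets, 8 of 24 tested members rose and 7 fell (camera adjusted p = 0.720), with RRM2B at 0.67, SPATA18 at 0.67, BTG2 at -0.75 and XPC at -0.59. Of the BCL2 family and caspases, 9 of 26 tested members rose and 7 fell (camera adjusted p = 0.587). The pro-apoptotic gene BMF fell to 1.89 ± 0.286 against 20.2 ± 0.385 CPM and HRK fell by 3.85, while BOK and BAD rose by 1.04 and 0.76. Of the shelterin and telomere genes, a process TRIP6 has been linked to, 4 of 12 tested members rose and 1 fell (camera adjusted p = 0.505), with STN1 at 0.72 and CTC1 at 0.27. The call of CTC1 was lost without shControl replicate 2 (adjusted p = 0.0596, in a range of 0.000716 to 0.0596 over its alternatives).

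Targets of the oxidative stress factor NRF2 were lower as a group. In this list 6 of 20 tested members rose and 12 fell (camera adjusted p = 3.72e-08, and adjusted p = 0.0508 with an estimated correlation). The quinone reductase gene NQO1 stood at 1.57 ± 0.310 CPM in shTRIP6 against 184 ± 9.58 CPM in shControl and the aldo-keto reductase gene AKR1C1 at 1.14 ± 0.237 against 135 ± 9.19 CPM. SRXN1 and the ferritin light chain gene FTL rose by 1.09 and 0.51. AKR1C1 has near-identical paralogs that its reads can be shared with. The call was lost in limma-voom (adjusted p = 0.0622) and without the genes at 5% or less of the shControl level (adjusted p = 0.0968), in a range of 5.54e-11 to 0.0968 over the camera alternatives. Of the ATF4 targets, 7 of 21 tested members rose and 11 fell (camera adjusted p = 0.0422, and adjusted p = 0.532 with an estimated correlation). The serine synthesis gene PSAT1 fell to 0.838 ± 0.0397 against 76.5 ± 6.03 CPM and ALDH1L2 fell to 0.0319 ± 0.0322 against 2.66 ± 0.498 CPM. The asparagine synthetase gene ASNS and MTHFD2 rose by 0.89 and 0.58. The ATF4 call held in 7 of 15 camera alternatives (adjusted p from 0.00430 to 0.316). It was lost in limma-voom (0.316), without the genes at 5% or less of the shControl level (0.210), with upper-quartile scaling (0.0527) and with the filter of 1 CPM in 3 libraries (0.0564). It was also lost without shTRIP6 replicate 1 (0.0558), shTRIP6 replicate 3 (0.0545), shControl replicate 2 (0.0572) or shControl replicate 3 (0.0533).

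The other metabolic and stress lists did not pass the camera test in edgeR. Of the cholesterol synthesis genes, 6 of 23 tested members rose and 11 fell (adjusted p = 0.273). HMGCS1, an early enzyme of this pathway, fell to 63.4 ± 1.33 against 151 ± 9.13 CPM. TM7SF2 and PMVK rose by 0.98 and 0.57. Of the fatty acid synthesis genes, 3 of 12 tested members rose and 5 fell (adjusted p = 0.695), with the desaturase genes SCD at -1.13 and FADS2 at -1.44 and with ELOVL6 at 0.94 and MID1IP1 at 0.50. Of the hypoxia and glycolysis genes, 17 of 29 tested members rose and 5 fell (adjusted p = 0.105), with ENO2 at 1.35, PDK1 at 0.79, ALDOC at -3.47 and VEGFA at 29.1 ± 1.38 against 64.9 ± 2.24 CPM. Of the nuclear-encoded oxidative phosphorylation genes, 15 of 28 tested members rose and 3 fell (adjusted p = 0.105), with COX6C at 0.75, NDUFB8 at 0.44, NDUFB5 at -0.33 and SDHA at -0.25. Of the FOXO targets, 3 of 16 tested members rose and 11 fell (adjusted p = 0.225), with SESN3 at -5.46, PIK3IP1 at -2.33, KLF2 at 0.78 and KLF6 at 0.39. For autophagy and lysosome genes, 10 of 22 tested members rose and 3 fell (adjusted p = 0.414), with the kinase gene ULK1 at 39.1 ± 1.40 against 101 ± 4.49 CPM, GABARAPL1 at -0.33, ATP6V1H at 0.64 and CTSL at 0.49. For chaperones of the endoplasmic reticulum, 7 of 20 tested members rose and 9 fell (adjusted p = 0.757), with DNAJB9 at 0.62, CRELD2 at 0.52, PDIA4 at -0.41 and DNAJB11 at -0.36. For cytosolic heat shock genes, 7 of 13 tested members rose and 4 fell (adjusted p = 0.567), with HSPA1A at -0.55, HSP90AA1 at -0.37, HSPA4L at 0.43 and HSF1 at 0.35.

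Interferon-stimulated genes divided in direction. Of these, 4 of 24 tested members rose and 11 fell (camera adjusted p = 0.130). The restriction factor gene BST2 fell to 1.08 ± 0.376 against 65.0 ± 4.11 CPM and IFI44L fell to 0.105 ± 0.110 against 4.71 ± 0.371 CPM. IRF7 and IFIT1 rose by 0.84 and 0.60. Of the MHC class I presentation genes, 4 of 9 tested members rose and 4 fell (camera adjusted p = 0.933), with the peptide transporter gene TAP1 at 0.71, PSMB8 at 0.52, HLA-C at -0.82 and ERAP1 at -0.73. Of the leukocyte markers, 2 of 3 tested members rose and 0 fell (camera adjusted p = 0.490), and the members that rose, CD14 and CORO1A, were at 2.22 ± 0.540 against 0.520 ± 0.189 CPM and 4.39 ± 0.953 against 1.98 ± 0.675 CPM. Too few endothelial markers had enough counts for a list test: ESAM rose to 3.83 ± 0.257 against 0.816 ± 0.0515 CPM and PECAM1, named after its values were seen, had no count in shTRIP6, at least 51.9-fold lower than its 1.65 ± 0.0650 CPM in shControl. None of the 13 mitochondrially encoded genes fixed as a sign of RNA quality was among the symbols analysed here.

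**Figure D3:**
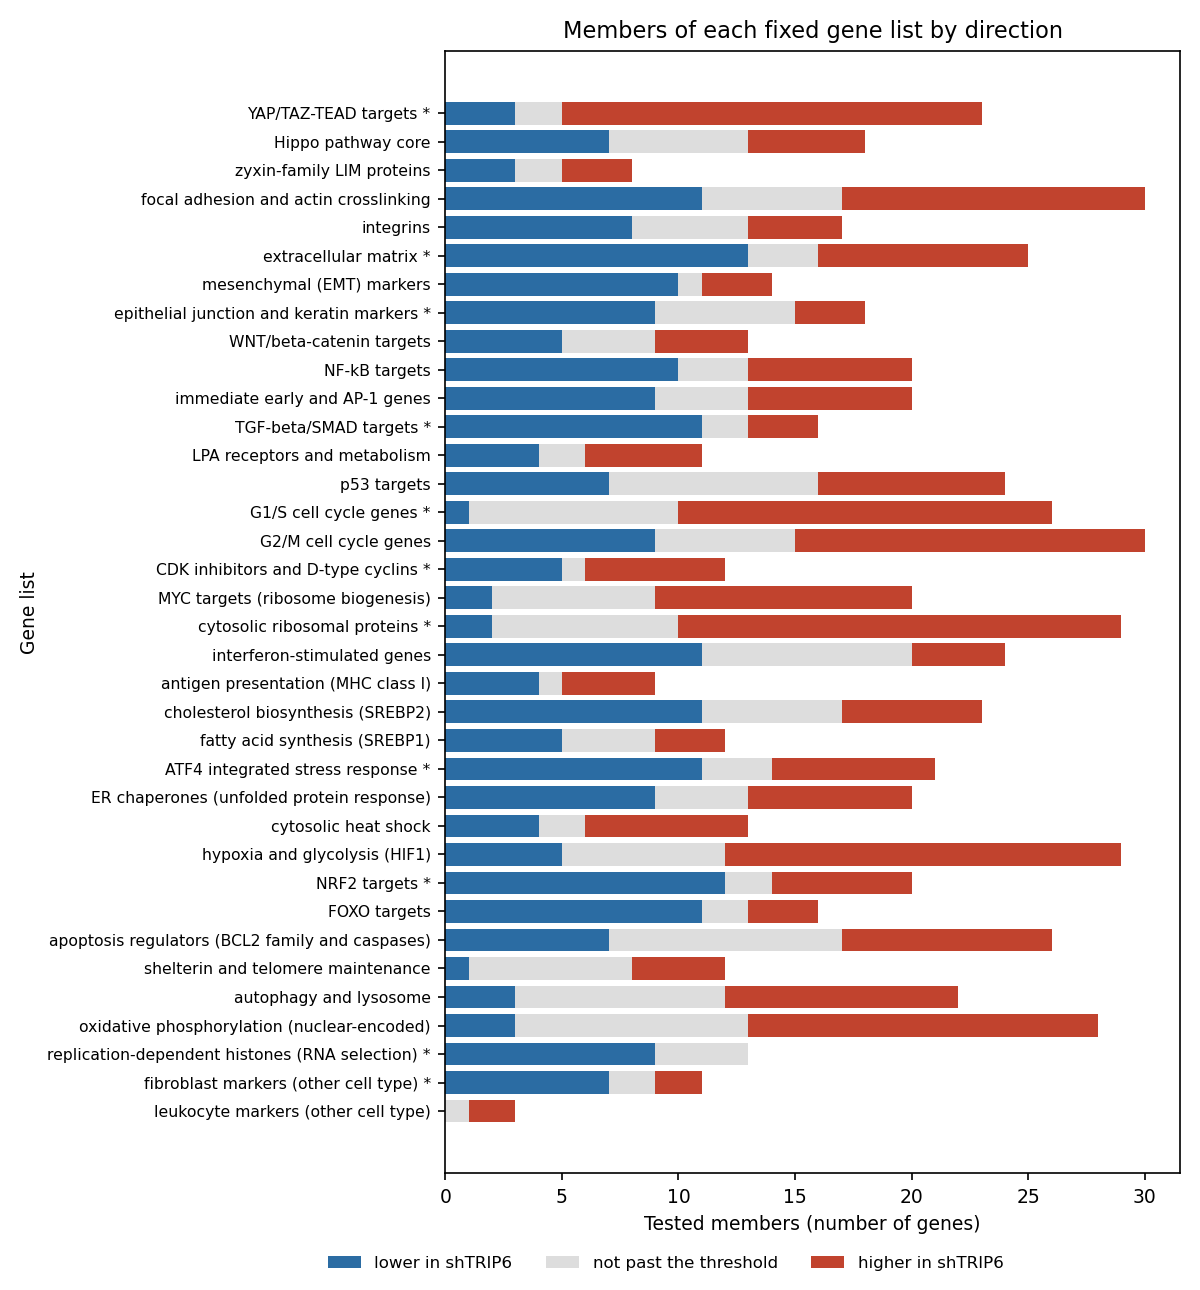
Number of tested members of each of the 36 tested gene lists that were lower (blue), not past the threshold (grey) or higher (red) in shTRIP6; an asterisk marks the 11 lists past an adjusted p of 0.05 in camera with a preset correlation. YAP and TAZ targets have 18 red members of 23, and TGF-beta and SMAD targets 11 blue members of 16.

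In all, 11 of 36 lists passed camera with its preset correlation, 3 higher and 8 lower. With a correlation estimated from the 6 libraries 0 did, and 8 had an unadjusted p under 0.05; fry, which asks only whether the genes of a list move one way on balance, called 28. In limma-voom 3 further lists passed camera as higher: MYC targets (adjusted p = 0.0438, in a range of 0.0438 to 0.120 over the camera alternatives), hypoxia and glycolysis (0.0404, in 0.0404 to 0.117) and oxidative phosphorylation (0.0391, in 0.0391 to 0.171). Besides the CDK list, the median, mean and test of a list differed in sign in 6 lists, all of them not past the camera threshold in edgeR. The mean alone was negative for focal adhesion genes (-0.23), LPA genes (-0.03), hypoxia and glycolysis (-0.02) and apoptosis regulators (-0.24). For endoplasmic reticulum chaperones the median alone was negative (-0.08), and for WNT targets the test alone was positive, with a median of -0.02. Adjusted over the list alone, the counts of higher and lower members were those given above except for focal adhesion (14 and 12), integrins (4 and 9), p53 targets (8 and 8), G1/S genes (16 and 2), ribosomal proteins (20 and 2) and hypoxia and glycolysis (17 and 6).

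Genes nearly absent from shTRIP6 included neighbours on chromosomes 9 and 13, which were looked at after the values had been seen. On chromosome 9 (GRCh38, 21480839 to 22455740) the 5 tested protein-coding genes IFNE, MTAP, CDKN2A, CDKN2B and DMRTA1 all stood at 1.39% or less of the control level. MTAP, an enzyme of methionine salvage, was at 0.552 ± 0.0846 CPM in shTRIP6 against 42.3 ± 1.56 CPM in shControl, while the flanking genes KLHL9 and TUSC1 had log2 fold changes of -0.16 ± 0.07 and 0.28 ± 0.09. On chromosome 13 (19633681 to 20903048) the 9 tested protein-coding genes from MPHOSPH8 to XPO4 stood at 3.76% or less, with ZMYM2 at 0.138 ± 0.0358 CPM in shTRIP6 against 13.1 ± 1.49 CPM in shControl and XPO4 at 0.170 ± 0.0805 against 14.4 ± 1.43 CPM, while the next gene, LATS2, was at 39.9 ± 2.84 against 39.1 ± 1.56 CPM. Of these 9, GJA3, CRYL1, IFT88 and EEF1AKMT1 stood at only 0.567 to 0.764 CPM in shControl, with 1 or 2 counts over the shTRIP6 group. They lie below the 1 CPM set for nearly absent genes, so their percentages are rough. The other 5 stood at 1.18% or less. IFNE and ZMYM5 had no count in shTRIP6 and were at least 34.9-fold lower and at least 54.7-fold lower against a floor of 3 counts over the group.

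**Figure D4:**
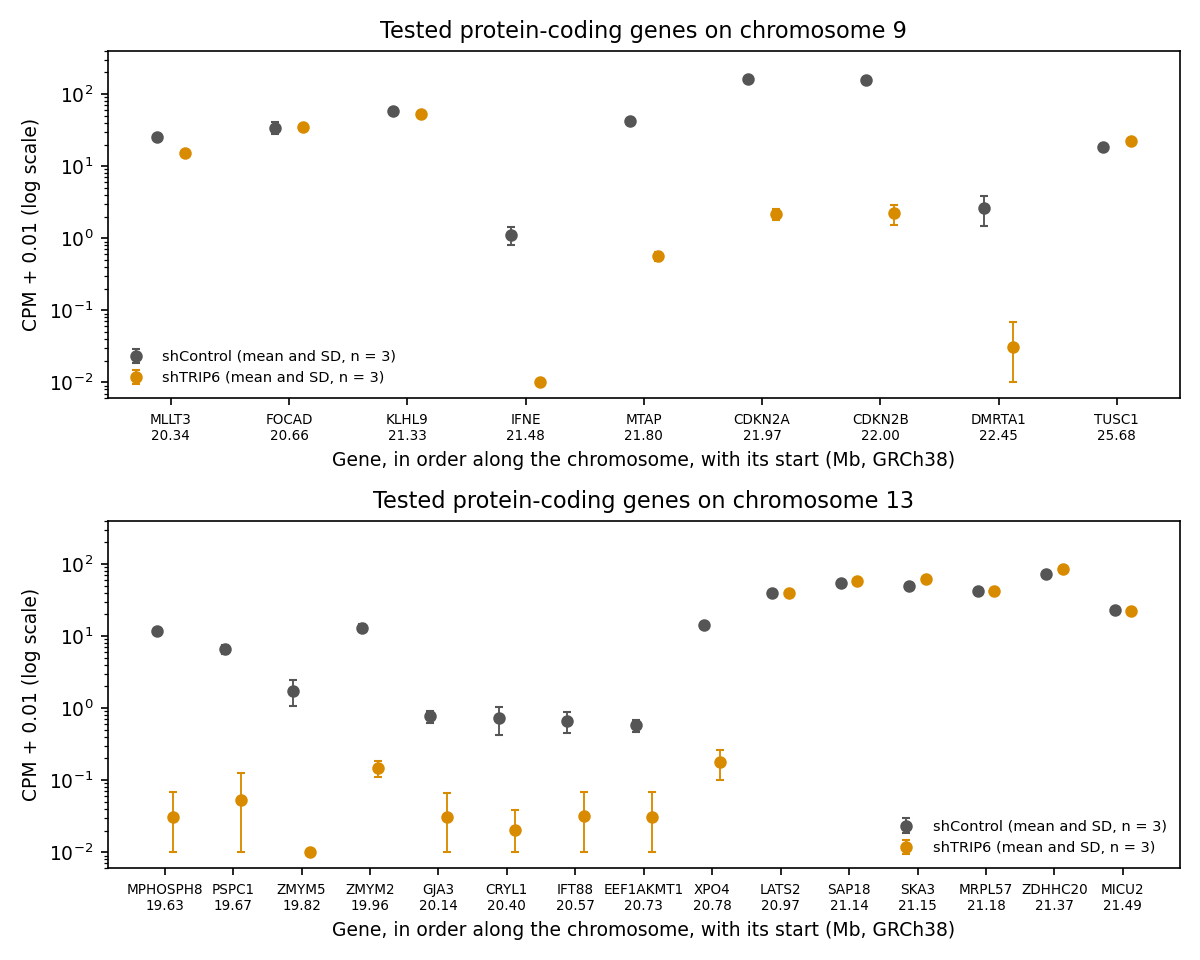
Mean CPM (0.01 added, log axis) of the tested protein-coding genes in order along parts of chromosomes 9 and 13, in shControl and shTRIP6, with the SD of 3 libraries as error bars that end at 0.01 where the SD exceeds the mean. Genes from IFNE to DMRTA1 and from MPHOSPH8 to XPO4 stand at 3.76% or less of the control level in shTRIP6, and flanking genes such as KLHL9 and LATS2 stand near it.

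Across the rest of the genome, neighbouring genes also differed together. In 203 windows of 50 neighbouring protein-coding genes, with nearly absent genes left out, the median log2 fold change ran from -0.51 on chromosome 9 (114402080 to 127578989) to 0.45 on chromosome 11 (167784 to 5612958). On chromosome 9, 6 of 8 windows lay below -0.2, and on chromosome 8, 4 of 7 lay above 0.2. The window that holds TRIP6 on chromosome 7 had a median of 0.17, while TRIP6 itself was at -2.04. Lists with small shifts, such as YAP and TAZ targets (median 0.31), G1/S genes (0.21) and ribosomal proteins (0.20), had medians within the range of these windows. A list is not a window of neighbouring genes, so this range does not test whether regional shifts explain the lists.

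**Figure D5:**
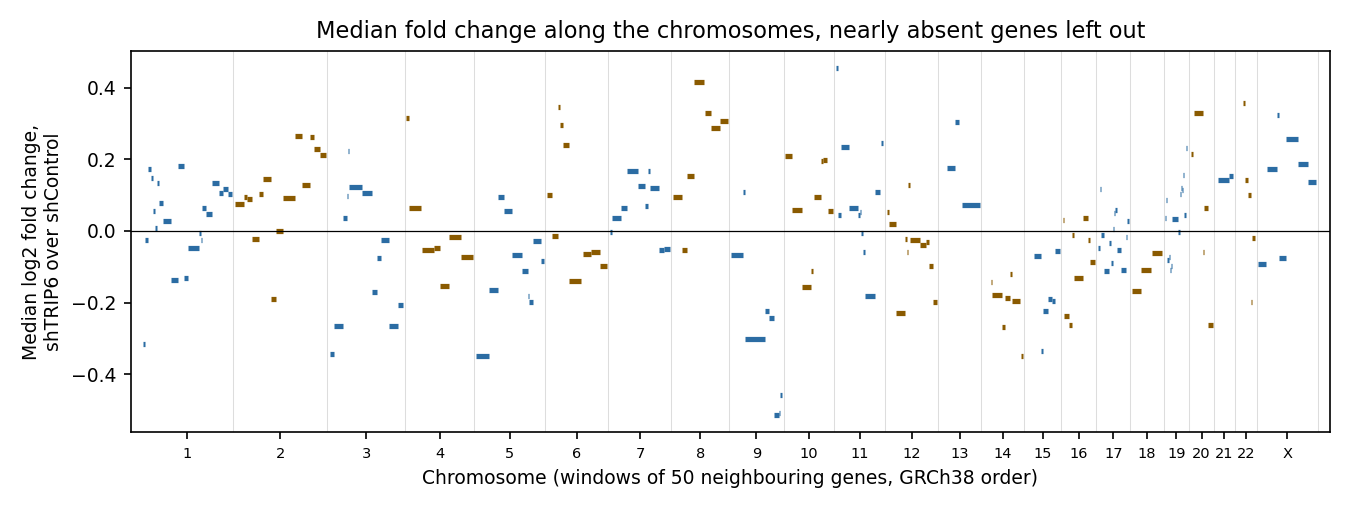
Median log2 fold change of shTRIP6 over shControl in 203 windows of 50 neighbouring genes along the genome, with genes at 5% or less of the shControl level left out; each horizontal line is a window and colours alternate by chromosome. The medians run from -0.51 on chromosome 9 to 0.45 on chromosome 11.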

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

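The comparison with only genes free of overlapping exons and the lists without genes at 5% or less of the shControl level were chosen after the data were seen. TRIP6 stayed lower and past the threshold under all 14 alternatives, at -2.10 to -1.98 on the log2 scale when each replicate was left out. Over the same 6 fits, 4018 to 4559 genes were higher and 4402 to 4919 lower, 632 to 726 were at least 2-fold higher and 1651 to 1694 at least 2-fold lower, and 10 to 11 lists passed. With other scalings, filters and tools, 4231 (DESeq2) to 5073 (upper quartile) genes were higher and 4368 to 5049 lower. Upper-quartile scaling turned the balance of calls, with 53.7% of them higher against 48.2% with TMM. Genes called both there and with the main settings had the same sign under every alternative run on all libraries or without a replicate. With only genes free of overlapping exons, 2840 were higher and 3196 lower, where fewer genes were tested. Of the 36 lists, 0 passed with an estimated correlation (8 at an unadjusted p under 0.05) and 28 passed in fry. In limma-voom 8 lists passed, 5 of them among the 11. The list of CDK inhibitors and D-type cyclins reversed its test direction without genes at 5% or less of the shControl level (median log2 fold change 0.29), since the 3 members left out were those that had fallen most. Of 2268 alternatives for named genes, 12 ended a call (CTC1, CXCL3, DKC1 and ORC1) and 0 reversed. With the replicate number as a block, 4377 genes were higher and 4702 lower, TRIP6 was at -2.04 and 11 lists passed. Deviations of libraries with the same number correlated at 0.02, 0.08 and -0.14, against up to 0.15 between different numbers, so a number did not link libraries. In simulated data with the same number of libraries and only 200 changed genes, 28% of 1.2-fold changes were recovered, which is not the power of the real comparison.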

Other observations

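The tests of scaling, of reads shared by overlapping genes or within families, of segment loss and both tests of carry-over were chosen after the result was seen. Genes in the opposite direction were few: 6 were nearly absent from shControl. Among them LZTS1 stood at 4.63 CPM in shTRIP6 with 2 counts over the shControl group, INSC at 2.44 with 2, WT1 at 1.69 with 4, HOXA7 at 1.64 with 7 and HSD11B1 at 1.09 with 3. The identity of the cells in either group was not tested.

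Besides the runs on chromosomes 9 and 13, 7 further runs of 3 or more neighbouring protein-coding genes stood at 5% or less of the shControl level. On chromosome 2 (233617645 to 233773310) a run held 9 UGT1A genes, which are counted over shared exons. On chromosome 19, runs of 8 zinc finger genes each lay from 52527652 to 52897693 and from 52928475 to 53496255, on either side of ZNF888 at -4.25. The others held CPVL, CHN2 and PRR15 on chromosome 7, CYSRT1, RNF224 and SLC34A3 on chromosome 9, C11orf86, SYT12 and RHOD on chromosome 11, and WISP2, KCNK15 and RIMS4 on chromosome 20. Genes next to these further runs were not all near the control level. Log2 fold changes were -3.01 for CREB5, -0.60 for RNF208, -0.85 for TUBB4B, -0.73 for LRFN4, -0.70 for KDM2A and -1.80 for ZNF331. USP40 (0.26), HJURP (0.49), SCRN1 (0.55) and ADA (0.71) were higher, ZNF480 (-0.35) lower and YWHAB (-0.05) near the control level.

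Genes nearly absent from shTRIP6 (441) outnumbered those nearly absent from shControl (6). Upper-quartile scaling, with 5073 genes called higher against 4487 under TMM, left 436 against 6. This ratio of 72.7 was the lowest of the 4 scalings run. The scalings moved the median log2 fold change of all genes only between -0.02 and 0.04. A fall to 5% is far larger, so they could not have removed the difference. They show only that the choice among these 4 scalings does not produce it. Fibroblasts in the shControl cultures were argued against by their abundant transcripts, with COL1A1 at 5.18 ± 0.287 CPM, COL3A1 at 2.36 and COL1A2 at 0.332 in shControl, below the median of 6.74 CPM of the nearly absent genes. Unequal admixture between the shControl libraries was argued against by the even level of these genes, whose median log2 deviation spanned 0.0277 over these libraries. An equal share of other cells or RNA in all shControl libraries would be as even, so it was not tested by this and stays open. For nearly absent genes outside the runs on chromosomes 9 and 13, and for the smaller changes of genes and lists, several explanations stay open. They include depletion of TRIP6, effects of the hairpin on other transcripts, and groups grown from different subclones or stocks of cells. Copy-number change that arose during selection, and the equal share of other cells or RNA named above, stay open as well. The design gives all of these the same split. In the runs on chromosomes 9 and 13, all 5 and all 9 tested protein-coding genes stood at 3.76% or less of the control level. On chromosome 13, GJA3, CRYL1, IFT88 and EEF1AKMT1 were below 1 CPM in shControl, and the other 5 stood at 1.18% or less. The flanking genes KLHL9 (log2 fold change -0.16) and LATS2 (0.03) stood near the control level. These values argue against depletion or the hairpin acting on each of these genes on its own. An effect on the whole region, or different subclones or stocks, stays open for them. So do loss that arose during selection and an equal share of other cells or RNA in shControl.

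The nearly absent genes lay beside each other in 9 runs with 47 genes, against at most 4 runs in 10000 permuted gene orders (permutation p = 1e-04, the smallest they can give), which is consistent with loss of genomic segments in the shTRIP6 cells. Median changes of windows outside these genes had an SD of 0.171, against at most 0.0806 in 1000 permuted orders. A copy-number difference between the groups would give this, whether it came from different subclones or stocks or arose during selection. Permuting the order removes any likeness between neighbours, so the test cannot tell copy number from other causes that move neighbouring genes together. Reads shared by overlapping genes or families were argued against as the source of all runs, since 4 runs were left without such genes, against a 95th percentile of 1 in permuted orders (permutation p = 2e-04), a bound set after the result was seen, although the highest permuted order also gave 4. The UGT1A run kept 0 genes with no overlapping exons and the zinc finger runs kept 3 and 5, so shared reads cannot be told apart from loss in these runs. The test of all 9 runs took the UGT1A genes as separate genes, which makes that run look rarer than a single locus would. Silencing of whole regions was not tested against loss, and most of the 441 genes lay outside the runs.

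Of the nearly absent genes, 243 had 5 CPM or more in shControl and any count in shTRIP6. Their median residual level in shTRIP6 was 1.56% of the shControl level (interquartile range 1.05% to 2.42%). Genes with no count in shTRIP6, such as IFNE and ZMYM5, were left out of this median. Carry-over of shControl cells, RNA or reads was not excluded, since 0 of 8276 genes with 20 CPM or more in shControl stood below 0.25%. Of these, 111 were nearly absent. Under 20 CPM, MPHOSPH8 (11.8 CPM in shControl) stood at 0.181%, with 2 counts over the shTRIP6 group. The slope of log2 level in shTRIP6 on that in shControl was 1.01 (95% bootstrap interval 0.93 to 1.08) and decides nothing, because the genes were chosen by their ratio to shControl, which draws it towards 1. A second comparison, made after the slope had been seen, argued only weakly against carry-over at 1 rate as the only source. The 5 genes of the chromosome 9 run kept 1.35 ± 0.0874% and the 9 of the chromosome 13 run 0.889 ± 0.170%. The chromosome 13 value was lower in all 3 shTRIP6 libraries (Fisher's exact p = 0.00877, two-sided, for counting error only). It rests on 42 counts, and replicates differed by more than counting error, so this p is likely too small. Carry-over at unequal rates or together with another source stays open.

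Of the 10 splits of the 6 libraries into groups of 3, only 1, the real split, gave 4487 higher and 4820 lower genes, and the highest of the others gave 0 and 0. These splits are too few for a share under 0.05.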
